A study of Mus musculus with 6 samples.

How the data were processed

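The samples were bulk RNA-seq libraries of CD11b+ spleen cells from 6 mice, 3 per group, with groups, replicate numbers and sex taken from the sample labels, which give each library its own mouse. Per the labels' protocols, B cells were cultured for 48 h before transduction, total RNA was extracted with a column kit without removal of genomic DNA on the column, 8 to 16 ng of RNA entered a low-input cDNA kit with 17 cycles of cDNA amplification, and 20 ng of cDNA entered library preparation with 9 further cycles. The labels describe no molecular identifiers, so amplified copies are counted as reads and any counting error is a lower limit. The kit is not described as keeping strand, so reads of overlapping and antisense genes could not be told apart.

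The submitters' processing notes name FastQC 0.74, cutadapt 4.4, STAR 2.7.10b, featureCounts 2.0.3, DESeq2 2.11.40.7 and the mouse builds GRCm38 and mm10, without roles or order. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited signal values are normalized counts, 1 column per library and 1 row per Ensembl gene (43432 genes), which the file headers trace to featureCounts. The authors divided whole read counts by 1 size factor per library: dividing each deposited column by its step gave whole numbers for 100% of values within a tolerance of 0.001, with a largest deviation of 2.7e-09. The recovered totals were 6490868, 6611212 and 5196339 reads for IgHMOG iGBGFP replicates 1, 2 and 3 and 5955142, 7564254 and 6396013 for WT iGB6 replicates 1, 2 and 3. The single most abundant gene held 4.51 to 12.3% of a library's normalized counts and the 10 most abundant held 17.3 to 34.9%. A gene at 0 in a library is compatible with up to 3 reads, or 2.37 to 3.56 normalized counts, for counting error alone. The second deposited table holds the authors' DESeq2 comparison without a header: a log2 fold change of WT iGB6 over IgHMOG iGBGFP and its standard error, a Wald score, a p-value and an adjusted p-value, the last for 10537 genes. The order of these deposited columns was read from the values, and the authors' log2 fold changes were smaller in size than those of limma for all 79 called genes that the naming rule below picks. A word in that table's name says that gender was taken into account, and the formula is not given in the sources used here.

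Gene symbols, coordinates (1-based) and gene types came from the GENCODE M21 annotation of GRCm38, matched on the Ensembl identifier for 42462 of 43432 genes. The other 970 kept their identifier. List members whose symbol was found for no gene of the table (Ahsp, Gbp5, Gbp6, Lilrb4a, Lilrb4b, Ly49q, Ly6a2, Nox2 and Rigi) were not measured. Near-identical copies share reads in ways that the authors' counting could split, so some such genes are called uncertain where named. Genes were not screened for copies, so a gene without that mark, such as Hbb-bs or Klra4, is not thereby free of the problem.

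The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend) on log2(normalized count + 1), for the 9923 genes with a mean normalized count of at least 10, with group and sex as terms, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes, and SE is limma's moderated standard error. Because the deposited values are normalized rather than raw counts, a log-scale test was the main one, and edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads were alternatives. They called 606 and 951 genes, of which 564 and 596 were among the 607 of limma. A second limma model added the interaction of sex and group. Sex and replicate number 1 coincide, so the sex term also takes up anything else that replicates numbered 1 shared.

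Gene lists (39, with 706 distinct genes, of which 697 matched a symbol and 558 were tested) were fixed before the data were examined, as were the designs, the alternatives and the rule for named genes. The rule took Il6 and the sex genes, the 12 largest rises and 12 largest falls among called genes with a mean of at least 100 and no overlap of the groups (predicted genes, pseudogenes and antigen receptor segments left out), and from each list up to 4 members with the smallest p and, for other cell types, the 2 most abundant. Of these, 1 gene is not reported here. Other called members named beside them, and members of a list singled out for their function, were chosen after their values were seen. The 36 lists with at least 5 measured members (sex genes apart) were tested with camera at a preset correlation between genes of 0.01, which compares a list with the other genes, then with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance, all with Benjamini-Hochberg adjustment over the lists. Comparisons of a single value used a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3 libraries.

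Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, quantile normalization, upper-quartile rescaling, no sex term, the replicate number as a block, robust empirical Bayes, library weights, the authors' deposited table, edgeR and DESeq2, each library left out in turn, and males alone. The limma and camera steps were tested on simulated data: read counts of the same 9923 genes were drawn in 5 rounds with 200 genes changed. At a 2-fold change 41.6% of the changed genes were called and at a 4-fold change 94.4%, each with the right sign, with 5.86% of calls false, and 0 calls by limma where nothing was changed. With 1 list moved, camera called that list (adjusted p = 1.23e-22) and 0 others, but the simulated genes were drawn independently, so calls among correlated genes were not tested. Across genes, the log2 fold change had a rank correlation of -0.079 with GC content and -0.0058 with gene length, known for 99.7% of genes. Plots were drawn with matplotlib in Python.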

Results

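RNA was sequenced in bulk from CD11b+ cells sorted from the spleens of 6 Rag1-KO mice of the C57BL/6J strain, 8 days after cell transfer. CD11b is an integrin chain carried mainly by neutrophils, monocytes, many macrophages and a subset of dendritic cells, and Rag1-KO mice make no mature T or B cells of their own. Every mouse received 2D2 CD4+ T cells, whose transgenic receptor recognises myelin oligodendrocyte glycoprotein (MOG), together with MOG-loaded B cells from the iGB culture, in which B cells take on a germinal centre-like state. In the WT iGB6 group (3 mice) these B cells were wild type and carried a retroviral vector with the Il6 gene and a green fluorescent protein. In the IgHMOG iGBGFP group (3 mice) they carried the MOG-specific IgHMOG heavy chain and the empty vector. B cell genotype and vector therefore changed together between the groups. Replicate 1 was a female and replicates 2 and 3 were males in both groups. Library depth ran from 5196339 to 6611212 reads in IgHMOG iGBGFP and from 5955142 to 7564254 reads in WT iGB6. Between 14816 and 17013 genes were detected per library.

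Il6 itself was barely detected in the sorted CD11b+ cells, which are not the cells that carried the vector. The Il6 gene (ENSMUSG00000025746, GRCm38 chromosome 5, 30013114 to 30019981) had 9, 20 and 6 reads in IgHMOG iGBGFP replicates 1, 2 and 3 and 3 reads in each WT iGB6 library. Its normalized counts were 10.8 ± 5.80 and 3.10 ± 0.64 (SD, n = 3 per group), with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow. Xist marked the sexes as labelled, at 244 and 211 normalized counts in the females and 0 to 1.00 in the males, and Ddx3y was at 296 to 430 in the males and at 0 in the females.

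The comparison asks how splenic CD11b+ cells differed between mice given IL-6-producing wild-type B cells and mice given IgHMOG B cells with the empty vector. Genes of neutrophil precursors and of cell division were higher in WT iGB6 mice, while genes of basophils, dendritic cells, MHC class II presentation and the immediate early response were lower. Saa3, an acute-phase serum amyloid gene, had the largest rise among the genes that the naming rule picks, from 34.1 ± 35.9 to 1112 ± 82.3 normalized counts (SD, n = 3 per group; log2 fold change 5.53, SE 0.48, adjusted p = 0.00157). Cd209a, a C-type lectin of dendritic cells, had the largest fall among them, from 511 ± 340 to 33.1 ± 32.2 (log2 fold change -4.24, SE 0.41, adjusted p = 0.00157). Each of these gene lists was called by camera with its preset correlation between genes and lost that call when the correlation was estimated from the data (adjusted p = 0.309 with an estimated correlation in each).

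Among the 12 genes with the largest rises, 6 belong to the list of neutrophil primary granule and precursor genes, which are made at the promyelocyte and myelocyte stages of neutrophil development. Mpo, the myeloperoxidase of primary granules, rose from 459 ± 213 to 5334 ± 3271 normalized counts (log2 fold change 3.39, SE 0.44, adjusted p = 0.00622). The neutrophil serine proteases Elane (2.61, SE 0.46), Prtn3 (2.42, SE 0.41) and Ctsg (2.34, SE 0.41) rose on the log2 scale, as did Ms4a3 (2.21, SE 0.26) and the ficolin Fcnb (1.88, SE 0.19). Other rises were those of F11r, a junctional adhesion molecule (2.39, SE 0.25), Spp1, which encodes osteopontin (2.33, SE 0.23), Gatm, an enzyme of creatine synthesis (1.73, SE 0.17), and the ectoenzyme Cd38 (1.71, SE 0.30). Saa3 lies on chromosome 7 at 46711998 to 46715700, Mpo on chromosome 11 at 87793581 to 87804413 and Fcnb on chromosome 2 at 28076378 to 28084885, all protein-coding genes of GRCm38.

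After Cd209a, the largest falls were those of basophil genes. Cd200r3, a receptor of basophils and mast cells, fell from 356 ± 122 to 52.4 ± 27.2 normalized counts (log2 fold change -2.86, SE 0.27, adjusted p = 0.00157). Cyp11a1, a steroid-synthesis enzyme also expressed by mast cells and basophils, changed by -2.83 (SE 0.34), and Fcer1a, the alpha chain of the IgE receptor, by -2.55 (SE 0.33) on the log2 scale. Fn1, which encodes fibronectin, changed by -2.55 (SE 0.37), the SLAM family receptor Slamf8 by -2.26 (SE 0.34), and Pid1 by -2.22 (SE 0.32). The chemokines Ccl3 (-2.26, SE 0.33) and Ccl4 (-2.15, SE 0.46), the phosphatase Dusp1 (-2.20, SE 0.51), the heat shock gene Hspa1a (-2.43, SE 0.32) and the myeloid lectin Clec4d (-2.14, SE 0.48) completed the list. Hspa1a has a near-identical copy, Hspa1b, so its count is uncertain. In the authors' deposited table, Dusp1 (adjusted p = 0.0967) and Clec4d (adjusted p = 0.125) did not pass. Cd209a lies on chromosome 8 at 3743397 to 3748984 and Cd200r3 on chromosome 16 at 44943678 to 44981380, both protein-coding.

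**Figure D1:**
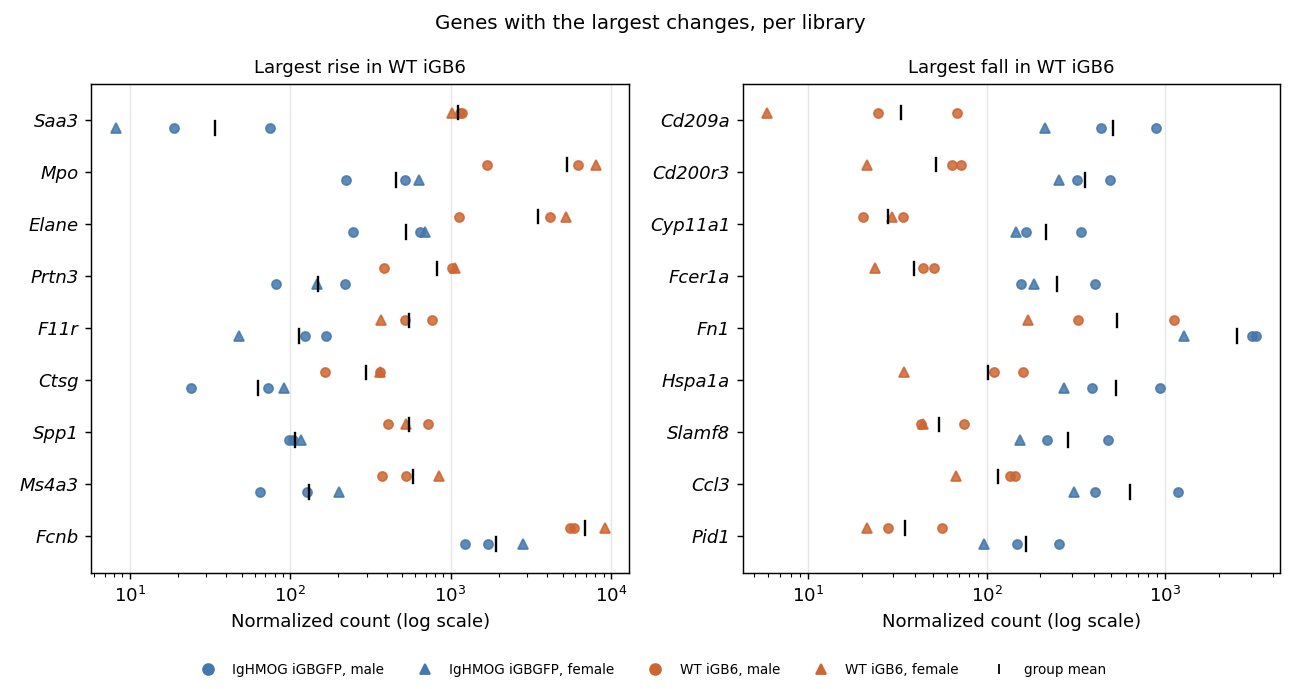
Normalized counts (log axis) of the 9 genes with the largest rise and the 9 with the largest fall in WT iGB6, with 1 point per library, triangles for the females, circles for the males and a black bar at each group mean. In each gene the 3 libraries of one group lie above the 3 of the other, as the selection rule required, and Saa3 runs from a mean of 34.1 to a mean of 1112.

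Of the 12 measured neutrophil primary granule and precursor genes, 9 rose, none fell and 3 did not pass, with 11 higher when adjusted over the list alone, and the median log2 fold change was 1.75 (camera adjusted p = 8.81e-10; adjusted p = 0.309 with an estimated correlation). Cebpe, a transcription factor of granulocyte maturation, rose by 1.14 (SE 0.29) and Serpinb1a, an inhibitor of neutrophil proteases, by 1.08 (SE 0.26). Among 17 neutrophil secondary and tertiary granule genes, 2 rose, Orm1 (1.14, SE 0.27) and Itgb2l (1.11, SE 0.27), and 15 did not pass, with 3 higher when adjusted over the list alone. That list had a median of 0.65 (camera adjusted p = 1.86e-04; adjusted p = 0.533 with an estimated correlation), and its most abundant gene, Ngp, was at 0.90 (SE 0.47, adjusted p = 0.266). These granule genes held 17.6 ± 5.86% of all normalized counts in IgHMOG iGBGFP and 25.8 ± 4.38% in WT iGB6 (SD, n = 3 per group), with overlapping libraries. Of 21 mature neutrophil genes, 3 fell, Clec4d, the chemokine receptor Cxcr2 (-0.90, SE 0.21) and the stefin Stfa2l1 (-2.02, SE 0.50; one of a family of close copies, so uncertain), and 18 did not pass. Adjusted over the list alone, 7 mature neutrophil genes were lower and 1 was higher, and the list was not called (median -0.16, camera adjusted p = 0.104), but it was called lower in 9 alternatives (adjusted p = 0.00222 without IgHMOG iGBGFP replicate 3 to 0.0404 with the replicate block).

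Genes of DNA replication and mitosis moved together. Of 36 measured members, 27 rose and none fell, with 34 higher when adjusted over the list alone, and the median log2 fold change was 1.12 (camera adjusted p = 4.4e-24; adjusted p = 0.309 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 656 ± 145 to 1874 ± 569 normalized counts (1.49, SE 0.18, adjusted p = 0.00471). The spindle gene Tpx2 (1.46, SE 0.20), the cyclin Ccnb2 (1.14, SE 0.17) and thymidylate synthase, Tyms (1.36, SE 0.21), also rose.

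Genes of basophils and mast cells fell in WT iGB6: 7 of 11 fell, 1 rose and 3 did not pass. With 9 lower and 1 higher when adjusted over the list alone, the list had a median of -1.93 (camera adjusted p = 8.4e-08; adjusted p = 0.309 with an estimated correlation). Beside the genes above, Ms4a2, the beta chain of the IgE receptor, went from 236 ± 8.21 to 63.6 ± 19.2 normalized counts (log2 fold change -1.92, SE 0.23), and Gata2, Cpa3 and Il6ra fell. Kit, a receptor of mast cells and progenitors, rose (1.04, SE 0.27), but did not pass with edgeR (adjusted p = 0.0571). The list's most abundant gene, Hdc, which neutrophils also express, was at -0.13 (SE 0.23, adjusted p = 0.768). Prss34, the next most abundant, did not pass either (-1.97, SE 0.72, adjusted p = 0.126), nor did Mcpt8. Both overlapped between the groups. Prss34 was at 675 normalized counts in IgHMOG iGBGFP replicate 3 and 249 to 1173 in WT iGB6. Mcpt8 was at 142 in that replicate and 66.4 to 165 in WT iGB6. Of 13 conventional dendritic cell genes, 6 fell, 1 rose and 6 did not pass. With 9 lower and 2 higher when adjusted over the list alone, the list had a median of -1.17 (camera adjusted p = 1.44e-04; adjusted p = 0.309 with an estimated correlation). Dpp4 (-2.31, SE 0.42), the transcription factor Irf4 (-2.55, SE 0.49), the cytokine receptor Flt3 (-1.98, SE 0.40) and Irf8 (-1.17, SE 0.24) fell, and Ffar2, a short-chain fatty acid receptor that neutrophils also express, rose (1.17, SE 0.26).

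MHC class II presentation genes fell in 7 of 12 cases, with none higher and 9 lower when adjusted over the list alone (median -1.39, camera adjusted p = 1.04e-07; adjusted p = 0.309 with an estimated correlation). Cd74, the invariant chain, changed from 19154 ± 10737 to 5540 ± 2904 normalized counts (log2 fold change -1.71, SE 0.31, adjusted p = 0.0174), and H2-Eb1 (-1.72, SE 0.25), H2-DMa (-1.57, SE 0.23) and H2-Aa (-1.70, SE 0.27) fell. For each of these the libraries of the groups overlapped, and the calls rest on the comparison within sexes. Of 17 MHC class I presentation genes, 0 were called by limma and 0 when adjusted over the list alone (median -0.30, camera adjusted p = 0.0088; adjusted p = 0.576 with an estimated correlation), and the call of that list was lost without WT iGB6 replicate 2 (adjusted p = 0.303).

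Monocyte genes were lower in part. Of 15 classical monocyte genes, 3 fell, Fn1, Ms4a4c (-0.85, SE 0.20) and Ms4a6c (-0.84, SE 0.21), and 12 did not pass. The most abundant member, Chil3, was higher without passing (1.26, SE 0.34, adjusted p = 0.054). Its normalized counts were 55862 ± 28617 and 125600 ± 29397. Chil3 passed as higher with edgeR (adjusted p = 0.0474), with DESeq2 (adjusted p = 1.88e-04) and in the authors' table (adjusted p = 1.19e-04). Classical monocyte genes held 1.78 ± 0.18% of normalized counts in IgHMOG iGBGFP and 2.42 ± 0.21% in WT iGB6. With 5 lower and 2 higher when adjusted over the list alone, the list had a median of -0.41 (camera adjusted p = 0.0465; adjusted p = 0.462 with an estimated correlation). That call was lost without the sex term (adjusted p = 0.139), with library weights (adjusted p = 0.0838), with edgeR (adjusted p = 0.0575), without IgHMOG iGBGFP replicate 3 (adjusted p = 0.127) and without WT iGB6 replicate 3 (adjusted p = 0.091). Of 14 non-classical monocyte genes, 5 fell and 9 did not pass. With 7 lower when adjusted over the list alone, the list had a median of -0.60 (camera adjusted p = 3.58e-05; adjusted p = 0.362 with an estimated correlation). They included Ace (-1.65, SE 0.27), the scavenger receptor Cd36 (-1.59, SE 0.28) and the fractalkine receptor Cx3cr1 (-1.87, SE 0.37). Of 21 red pulp and other splenic macrophage genes, 1 rose, Cd5l (1.47, SE 0.36), 20 did not pass and the list was not called (median -0.29, camera adjusted p = 0.162), with 1 higher when adjusted over the list alone. Without WT iGB6 replicate 2 it was called lower (adjusted p = 7.57e-05).

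**Figure D2:**
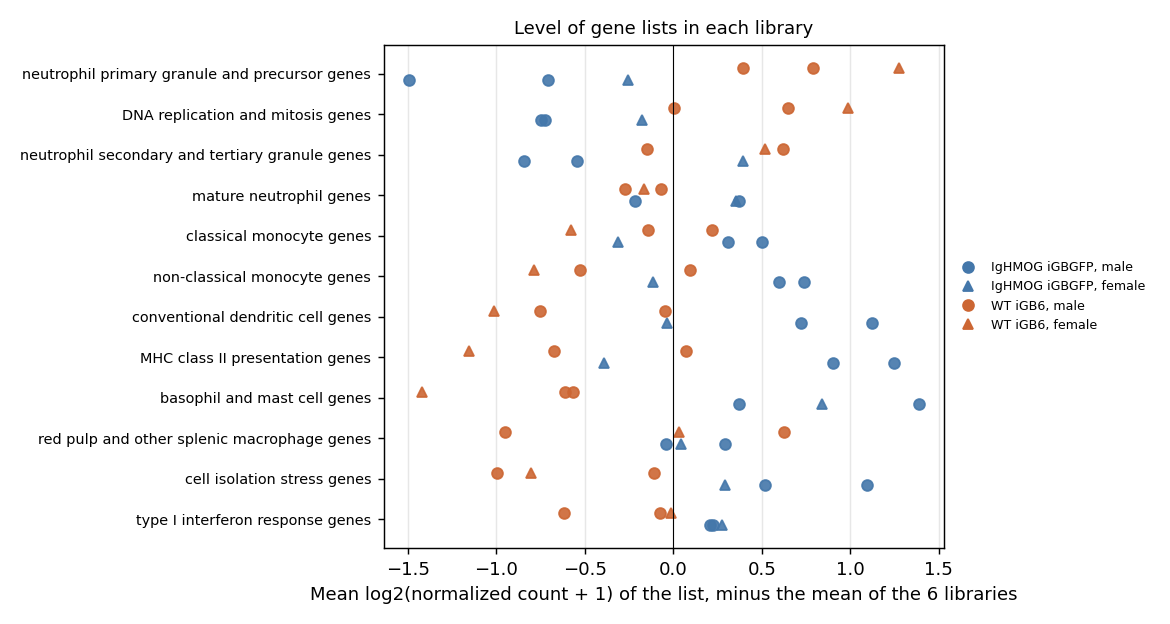
Mean log2(normalized count + 1) of the members of 12 gene lists in each library, minus the mean of the 6 libraries, with triangles for the females and circles for the males. Primary granule genes lay higher in every WT iGB6 library and basophil genes lay lower, while the groups overlapped for MHC class II genes.

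Cell isolation stress genes, a list of immediate early and heat shock genes that tissue handling is known to induce, fell in 10 of 19 cases and rose in none. With 14 lower when adjusted over the list alone, the list had a median of -1.44 (camera adjusted p = 7.79e-10; adjusted p = 0.309 with an estimated correlation). Junb (-1.44, SE 0.21), Atf3 (-1.48, SE 0.29) and Egr2 (-1.80, SE 0.36) were among them, and Fos, the most abundant called member, changed from 15194 ± 4888 to 5651 ± 3798 normalized counts (-1.58, SE 0.38, adjusted p = 0.0409). Of 23 IL-6 receptor and STAT3 target genes, 8 fell, 1 rose (Saa3) and 14 did not pass. With 9 lower and 1 higher when adjusted over the list alone, the list had a median of -0.66 (camera adjusted p = 1.16e-04; adjusted p = 0.362 with an estimated correlation). The fallen members included Junb, Tnfaip3, an inhibitor of NF-kappa B signalling (-1.50, SE 0.29), and Irf8. Il6ra, the IL-6 receptor alpha chain, changed by -1.09 (SE 0.23). Junb also stands in the isolation stress list, Irf8 in the dendritic cell list and Il6ra in the basophil list. In all, 8 of the 23 members stand in another list, so the fall of this list is not fully separate from theirs. The list without its shared members was not tested. Of 21 inflammatory cytokine and chemokine genes, 5 fell, Ccl3, Ccl9 (-1.26, SE 0.24), Ccl4, Ptgs2 (-2.12, SE 0.50) and Csf1, and 16 did not pass. Ptgs2 did not pass in the authors' table (adjusted p = 0.0976) or with DESeq2 (adjusted p = 0.0866). With 10 lower and 1 higher when adjusted over the list alone, the list had a median of -0.59 (camera adjusted p = 3.55e-04; adjusted p = 0.309 with an estimated correlation).

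Type I interferon response genes fell in 8 of 35 cases and rose in none. With 12 lower when adjusted over the list alone, the list had a median of -0.45 (camera adjusted p = 4.61e-06; adjusted p = 0.488 with an estimated correlation). Ifi27l2a (-1.19, SE 0.19), Ifit3 (-1.35, SE 0.24), Ifi204 (-0.94, SE 0.20) and Mx1 (-1.17, SE 0.26) had the smallest p-values in the list. Ifit3 and Ifi204 have close copies, so their counts are uncertain. Of 25 interferon gamma response genes, 1 fell, Irf1 (-0.85, SE 0.19), and 24 did not pass. With 1 lower when adjusted over the list alone, the list had a median of -0.38 (camera adjusted p = 6e-04; adjusted p = 0.492 with an estimated correlation).

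Few single genes of other cell types that the gate could hold passed the test. Of 8 T cell genes, Lat, an adaptor that mast cells and basophils also use, fell (-1.75, SE 0.30) and 7 did not pass. With 2 lower when adjusted over the list alone, the list had a median of -0.73 (camera adjusted p = 0.0216; adjusted p = 0.462 with an estimated correlation). The call of the T cell list was lost without IgHMOG iGBGFP replicate 3 (adjusted p = 0.0622), without WT iGB6 replicate 2 (adjusted p = 0.221) and with males alone (adjusted p = 0.0501), and its most abundant member, Cd3d, was at 80.9 ± 45.0 and 73.3 ± 11.3 normalized counts. None of 6 B cell genes passed. With 2 lower and 1 higher when adjusted over the list alone, the list had a median of -0.50 (camera adjusted p = 0.297). Of 5 plasma cell genes, Irf4 alone fell. With 2 lower when adjusted over the list alone, the list had a median of -0.88 (camera adjusted p = 0.0104; adjusted p = 0.309 with an estimated correlation). The plasma cell call was lost without the filter (adjusted p = 0.317) and in the authors' table (adjusted p = 0.0711), and IgHMOG iGBGFP replicate 3 stood apart, with Ighg1 at 214 normalized counts against 7.16 and 7.76 in replicates 1 and 2 and 1.19 to 7.87 in WT iGB6. Of 18 erythroid genes, 0 passed in limma and 0 when adjusted over the list alone (median 0.70, camera adjusted p = 0.0076; adjusted p = 0.618 with an estimated correlation), and that call was lost without IgHMOG iGBGFP replicate 3 (adjusted p = 0.412) and with library weights (adjusted p = 0.118). Nkg7, a granule protein of cytotoxic cells, rose (1.36, SE 0.22) and was the single called member of 15 natural killer cell genes, also when adjusted over the list alone (median -0.14, mean -0.05, camera adjusted p = 0.963), while the list was called higher without WT iGB6 replicate 2 (adjusted p = 0.00395) and lower without WT iGB6 replicate 3 (adjusted p = 0.00106). Of 5 eosinophil genes, Alox15 fell (-1.16, SE 0.26), also when adjusted over the list alone (median -0.64, camera adjusted p = 0.162), and the list was called lower without the filter (adjusted p = 0.00843) and in the authors' table (adjusted p = 0.0365). Of 7 megakaryocyte and platelet genes, Ppbp rose (1.98, SE 0.40) and Itga2b fell (-1.32, SE 0.32). With 2 higher and 1 lower when adjusted over the list alone, the list had a median of 0.38 (camera adjusted p = 0.259; adjusted p = 0.0382 without the filter). Of 8 stem and progenitor cell genes, Kit rose and Gata2 fell. With 4 higher and 1 lower when adjusted over the list alone, the list had a median of 0.35 (camera adjusted p = 0.413). The plasmacytoid dendritic cell list (4 genes measured) and the stromal and endothelial list (2 genes measured) were too small for a list test and held 0 genes called by limma, with 1 lower and 1 higher, respectively, when adjusted over the list alone.

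**Figure D3:**
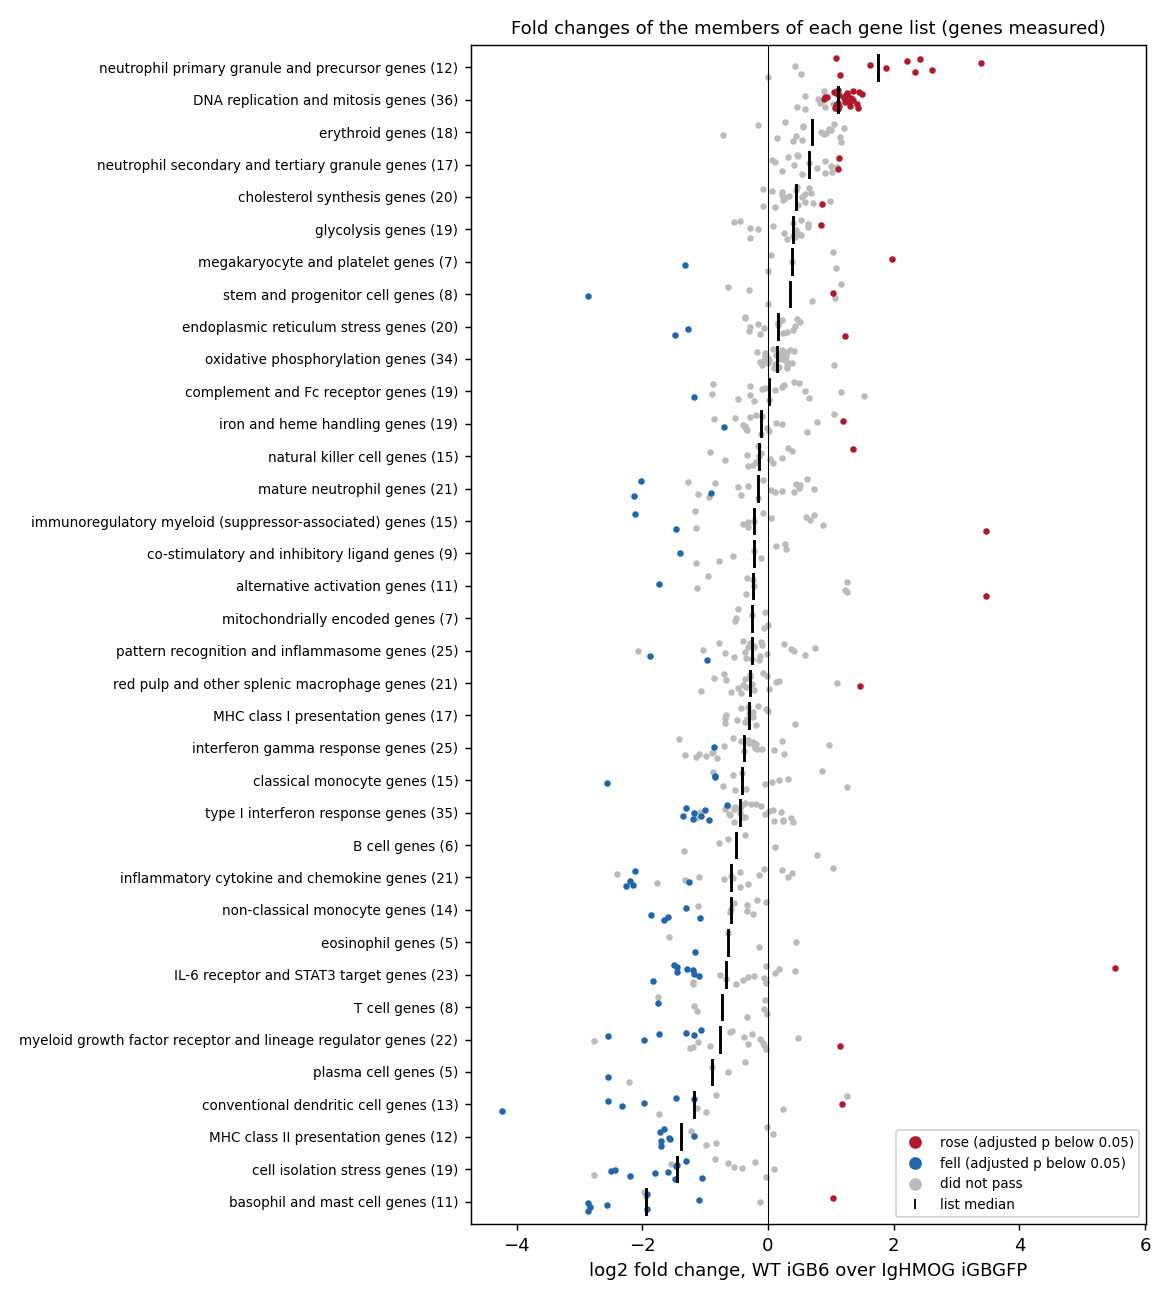
Log2 fold change, WT iGB6 over IgHMOG iGBGFP, of each measured member of the 36 tested gene lists, with members that rose in red, members that fell in blue, the rest in grey and the list median as a black bar. The medians run from -1.93 for basophil and mast cell genes to 1.75 for neutrophil primary granule and precursor genes.

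In limma, 607 of 9923 tested genes were called, 273 higher and 334 lower in WT iGB6, so that 45% were higher, against 227 higher and 465 lower (32.8% higher) after upper-quartile rescaling. Of these, 198 higher and 277 lower genes changed at least 2-fold. The 3 libraries of one group lay above the 3 of the other in 2341 genes (23.6%), among them 461 of the called genes. Chance gives 10% on average over splits, but genes move together and the share in the other splits was not computed, so an excess was not tested. The authors' deposited table called 862 genes, 410 higher and 452 lower, and 578 genes were called in both, each in the same direction. The authors' log2 fold changes were smaller in size for all 79 called genes that the naming rule picks: 2.41 against 5.53 for Saa3, 2.09 against 3.39 for Mpo, -3.33 against -4.24 for Cd209a and -1.56 against -2.55 for Fn1. For these genes edgeR on the recovered reads gave 5.10, 3.48, -4.04 and -2.40, nearer to limma. The cause of the gap was not tested. The list test called 21 of 36 lists, 6 higher and 15 lower, and 0 with an estimated correlation, where 1 list had an unadjusted p below 0.05. Other splits of the same 6 libraries into 3 and 3, which each keep 2 libraries of a group together, called 11 to 19 lists and 0 genes in limma. All 607 called genes had the same sign between the females and between the males. The fit that called them combines both sexes, so this agreement is largely built into the selection. The interaction of sex with group, which rests on 1 female per group, gave 0 genes in limma (148 at an unadjusted p below 0.05) and 0 in edgeR (143 at an unadjusted p below 0.05). The count of calls depended on single libraries and on the sex term: it was 10 without that term, 128, 4 and 28 without IgHMOG iGBGFP replicate 1, 2 and 3, and 133, 1090 and 657 without WT iGB6 replicate 1, 2 and 3. Of the 79 called genes that the naming rule picks, 39, 2 and 15 kept their call without IgHMOG iGBGFP replicate 1, 2 and 3 and 39, 76 and 73 without WT iGB6 replicate 1, 2 and 3, all with their direction, and Saa3 and Cd209a were the 2 that kept it without IgHMOG iGBGFP replicate 2.

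The libraries did not separate fully by group. On the first principal component (53.2% of the variance of the tested genes), IgHMOG iGBGFP replicates 2 and 3 lay at -44.3 and -44.6 and WT iGB6 replicates 1 and 3 at 48.2 and 35.0, while IgHMOG iGBGFP replicate 1 lay at 3.20 and WT iGB6 replicate 2 at 2.60. Across genes, which are not independent replicates, IgHMOG iGBGFP replicate 1 correlated with its own group at 0.953 and 0.942 and with the WT iGB6 libraries at 0.956, 0.958 and 0.954.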

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

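Alternatives were planned except edgeR with the replicate block, chosen after the data were seen. All 607 called genes that remained testable kept their direction in every setting run. These settings reuse libraries from which the genes were selected, so this is not independent support. The counts of calls, 273 higher and 334 lower, moved as follows, with the cause not tested unless given. Without a filter 459 were higher and 620 lower among 22665 genes, with library weights 731 and 712, with DESeq2 422 and 529, and the authors' deposited table gave 410 higher and 452 lower genes. Without the sex term 6 and 4 remained, although 605 of the 607 had an unadjusted p below 0.05, and with males alone, where 4 libraries were left, 61 and 72. With 1 library left out, the range was 3 to 410 higher and 1 to 680 lower, with the lowest counts without IgHMOG iGBGFP replicate 2 and the highest without WT iGB6 replicate 2. Leaving out either female lets the sex term take up the other, so those fits rest on the males. The pseudocounts, the mean of at least 50, quantile normalization, upper-quartile rescaling, robust empirical Bayes and edgeR without a block stayed within 1.5 times of both counts.

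With the replicate block, limma called 435 higher and 566 lower genes, which included all 607, and edgeR 378 and 571. For a check of pairing, each gene's group mean was subtracted, and the remaining deviations were correlated between libraries of different groups. These deviations correlated at 0.482, 0.35 and 0.0407 for same-numbered libraries 1, 2 and 3, against 0.287 for the highest other pairing. Of 6 libraries, 4 correlated best with their own number. Mouse numbers also lay close within a replicate number (729 and 727, 772 and 770, 790 and 788). Numbers 1 and 2 lean towards a pairing and number 3 does not, and number 1 also holds the females. A pairing is thus neither shown nor excluded, and the main model left it out.

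Lists called were 0 with an estimated correlation (1 with an unadjusted p below 0.05), 0 with fry in one direction (lowest adjusted p 0.107) and 17 to 25 in every other setting. The interaction of sex and group gave 0 genes in limma (148 at an unadjusted p below 0.05) but 1230 without a filter, all 1230 with a mean below 10.

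Medians of 6 lists and fold changes of 3 genes, none of them called in the main setting, changed sign. Of these lists, natural killer cell genes were called higher without WT iGB6 replicate 2 (adjusted p = 0.00395) and lower without WT iGB6 replicate 3 (adjusted p = 0.00106), macrophage genes lower without WT iGB6 replicate 2 (adjusted p = 7.57e-05) and mature neutrophil genes lower in 9 alternatives. For mature neutrophil genes the range with 1 library left out was -0.33 to 0.0036, for macrophage genes -0.76 to 0.26 (0.065 with library weights), for natural killer cell genes -0.89 to 0.62 (0.12 in the authors' deposited table, 0.15 with edgeR, 0.15 with DESeq2), for alternative activation genes -0.75 to 0.40 (0.22 with library weights) and for iron and heme genes -0.36 to 0.11 (0.053 with library weights). For complement and Fc receptor genes it was -0.037 to 0.18, with -0.017 without a filter, -0.050 at a mean of at least 50, -0.036 with quantile normalization, -0.054 with upper-quartile rescaling, -0.014 in males and -0.0051 with edgeR and the replicate block. Prg2 ranged from -3.13 to 0.10 (0.10 in males), Klra4 from -1.41 to 0.049 and Ccl5 from -1.01 to 0.34.

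Depth sets the floor of detection, 3 reads or 2.37 to 3.56 normalized counts. Over all tested genes, 2-fold changes were found in 41.6% of simulated cases, and how far depth or the spread between animals limits this was not tested.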

Other observations

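The tests of explanations in this part were chosen after the results were seen, except the counts of calls over other splits of the libraries, which were planned. The bar of 2 residual SD with the sex term was also added after the values were seen, and it left dilution of basophil genes open where 2 pooled SD alone had not.

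Few metabolic genes, a group not described above, were called. Of 20 cholesterol synthesis genes, Fdps, the farnesyl diphosphate synthase, rose (0.86, SE 0.17, adjusted p = 0.022) and 19 did not pass. With 3 higher when adjusted over the list alone, the list had a median of 0.45 (camera adjusted p = 7.61e-04; adjusted p = 0.309 with an estimated correlation). Of 19 glycolysis genes, Pgam1 rose (0.85, SE 0.19). With 4 higher when adjusted over the list alone, the list had a median of 0.41 (camera adjusted p = 0.0101; adjusted p = 0.431 with an estimated correlation), and that list's call was lost without WT iGB6 replicate 2 (adjusted p = 0.0533). None of 34 oxidative phosphorylation genes (median 0.14, camera adjusted p = 0.0641) and none of 7 mitochondrially encoded genes (median -0.26, camera adjusted p = 0.0823) passed in limma or when adjusted over the list alone, although the oxidative phosphorylation list was called higher without the filter (adjusted p = 0.00857), without the sex term (adjusted p = 0.0421), in the authors' table (adjusted p = 0.0107) and without IgHMOG iGBGFP replicate 2 (adjusted p = 7.18e-04), and the mitochondrial list lower with quantile normalization (adjusted p = 0.0454). Of 20 endoplasmic reticulum stress genes, the transcription factors Ddit3 (-1.27, SE 0.23) and Atf3 fell and Asns, the asparagine synthetase, rose (1.23, SE 0.23), the same numbers when adjusted over the list alone (median 0.15, mean -0.0063, camera adjusted p = 0.815). Of 19 iron and heme handling genes, the ferritin receptor Ncoa4 rose (1.20, SE 0.24) and the ferritin heavy chain Fth1 fell (-0.70, SE 0.18). With 2 higher and 1 lower when adjusted over the list alone, the list had a median of -0.11 (camera adjusted p = 0.803).

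Arg1, an arginase, was called higher and was near the detection floor in IgHMOG iGBGFP, at 0, 3.45 and 0 normalized counts against 26.1, 24.5 and 7.87 in WT iGB6 (adjusted p = 0.0339), while Arg2 fell (-1.46, SE 0.33). These and Ptgs2 were the called members of 15 immunoregulatory myeloid genes. With 5 higher and 4 lower when adjusted over the list alone, the list had a median of -0.22 (camera adjusted p = 0.646). Of 11 alternative activation genes, Arg1 rose and Klf4 fell (-1.73, SE 0.39). With 3 higher and 2 lower when adjusted over the list alone, the list had a median of -0.24 (mean 0.21, camera adjusted p = 0.988). Of 22 myeloid growth factor receptor and lineage regulator genes, 6 fell, among them Irf4, Flt3, Irf8 and Klf4, and Cebpe rose. With 12 lower and 2 higher when adjusted over the list alone, the list had a median of -0.76 (camera adjusted p = 5.17e-05; adjusted p = 0.309 with an estimated correlation). Of 25 pattern recognition and inflammasome genes, the beta-glucan receptor Clec7a (-1.88, SE 0.40) and Aim2 (-0.97, SE 0.24) fell. Clec7a did not pass in the authors' table (adjusted p = 0.0699) or with DESeq2 (adjusted p = 0.0597). With 3 lower when adjusted over the list alone, the list had a median of -0.26 (camera adjusted p = 0.0289; adjusted p = 0.531 with an estimated correlation), and that list's call was lost with library weights (adjusted p = 0.0886), with DESeq2 (adjusted p = 0.0711), without IgHMOG iGBGFP replicate 3 (adjusted p = 0.112) and without WT iGB6 replicate 3 (adjusted p = 0.0912). Of 9 co-stimulatory and inhibitory ligand genes, Havcr2 fell (-1.40, SE 0.28). With 2 lower when adjusted over the list alone, the list had a median of -0.23 (camera adjusted p = 0.112). Of 19 complement and Fc receptor genes, C3ar1 fell (-1.18, SE 0.26). With 1 higher and 1 lower when adjusted over the list alone, the list had a median of 0.02 (camera adjusted p = 0.803).

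The rise of DNA replication and mitosis genes could have come from several dividing cell types. Dividing T or B cells would have raised T and B cell genes by about as much, but the mean log2 level of those lists minus the mitosis list moved by -1.70 (pooled SD 0.754, no overlap of libraries, exact permutation p = 0.1, the smallest possible; p = 0.027 with the sex term), which argues against them. Erythroid precursors cannot be told apart, because the erythroid list minus the mitosis list moved by -0.47, less than its pooled SD of 0.786 (exact permutation p = 0.7) (Hbb-bs, the most abundant, was at 939 ± 633 and 1709 ± 728 normalized counts, although a CD11b gate would remove most erythroid cells). A larger number of neutrophil precursors among the sorted cells stays open and was not tested. Whether IL-6, the B cell genotype or both lie behind the rise was not tested either.

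The fall of basophil and dendritic cell genes might reflect only a larger share of neutrophils, which would lower the genes of every other cell type alike. For the basophil list relative to the splenic macrophage list, the difference of -1.54 between the groups (pooled SD 0.751, no overlap, exact permutation p = 0.1) was under 2 residual SD with the sex term (SE 0.66, p = 0.1), and WT iGB6 replicate 3, at 0.475, lay 0.027 below the lowest IgHMOG iGBGFP library. For dendritic cell genes the same difference was -1.01 (pooled SD 0.633, overlapping libraries, exact permutation p = 0.2), and with the sex term its SE was 0.38 (p = 0.077), with no overlap among the males. For both lists dilution cannot be told apart from a lower number or a changed state of those cells, since the libraries are too few for their spread. Of the measured members, 3 of 11 basophil genes, 5 of 13 dendritic cell genes and 8 of 21 macrophage genes also stand in another list. A biological difference between the groups stays open and untested for both.

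The fall of immediate early and heat shock genes, with a difference of -1.27 in the mean log2 level of the cell isolation stress list (pooled SD 0.441, no overlap, exact permutation p = 0.1), could come from handling. The labels give no time or order of isolation per mouse, so a difference in handling between the groups cannot be told apart from a change in the cells. Loss of the cell types whose genes fell also stays open: relative to the list that fell more, of basophil and dendritic cell genes, the stress list differed by 0.461 (pooled SD 0.476, overlapping libraries, exact permutation p = 0.3), by a rule that gained its outcome of a fit after this value was seen. The abundance of Fos and Zfp36, at 15194 and 14884 normalized counts in IgHMOG iGBGFP, is set beside this as a value only.

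Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 607 genes, and the highest of the others called 0. For gene lists 1 split, again the real one, called as many as 21, and the others called 11 to 19. With 10 splits a share under 0.05 cannot be reached. Each other split keeps 2 libraries of a group together and so carries part of the difference between the groups, so their list calls cannot be read as false calls. Of the 9 other splits, 4 put both females on one side, where the sex term leaves 1 male against 3, and 5 kept them apart, with 0 genes and 11 to 16 lists called. The real grouping gave the largest list median, in size, for 24 of 38 lists against those 5 splits and for 4 of 38 against all 9, a comparison added after the results were seen.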
